A study of Drosophila melanogaster with 2 samples.

How the data were processed

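Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where a GFP-tagged Sox102F protein sits on the fly genome. Per the labels, the flies were Drosophila melanogaster carrying Sox102F fused at its C terminus to GFP, collected as whole white prepupae of both sexes, and the antibody was raised against GFP. One label field names Sox102F itself as the antibody target, and the free-text description names GFP. Per the labels, chromatin was fragmented by sonication. The 2 samples form 1 group, biological replicates 1 and 4, and no second genotype, stage or untagged line was analysed here.

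The deposited files are peak lists in the narrowPeak layout, on genome builds dm6 and dm3. For each build there is 1 list for replicate 1, 1 for replicate 4, 1 for both replicates pooled, and 1 list named as optimal after thresholding by irreproducible discovery rate (IDR), a measure of rank agreement between replicates. The replicate and pooled lists hold 30000 entries each, so they include background. Per the text records deposited with the files, each list was made from alignments and a control, and the optimal list from the other 3. The aligner, the peak caller, the control's processing and the IDR threshold are not given in the sources used here. The optimal dm6 list was tested against the pooled dm6 list. Its 7055 entries are those at or above a signal of 76.7 in the pooled list, which holds 7055 entries at or above that value.

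The signal value of each peak is the authors' own, as deposited, and was used only to rank, describe or filter peaks within a list. The second column of values in the deposited lists is a −log10 q-value. It reaches a ceiling of 3.92 in the optimal dm6 list, shared by 58.9% of its peaks, so it was not used for ranking. The deposited position of the summit, given as an offset in bp from the peak's start, is another value used here. No read counts were used, so the depth of each library is unknown, and no interval printed here covers sequencing error. Confidence intervals (95%) are over peaks or genes, which are not replicates. With 2 replicates the spread is given as both replicates' own values.

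Coordinates are dm6, counted from 1. The gene annotation was Ensembl release 115 on assembly BDGP6.54, and the sequence was that of the release 6 assembly. Peak ends in the dm6 lists lie inside the arm lengths of that sequence. Only arms 2L, 2R, 3L, 3R, 4 and X were used, and transposable elements were left out of the annotation. The dm3 lists were used for counts, arms and replicate overlap alone, since dm3 was not annotated here.

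Summits were assigned to classes in a fixed order: within 500 bp of a transcription start, 5′ UTR, 3′ UTR, coding exon, other exon, intron, intergenic. Class shares, arm counts and distances were set against 1000 random placements of the same number of summits, two-sided, a permutation test for which the smallest p is 0.002. To compare replicates, the 7055 entries with the highest signal were taken from each, and summits within 100 bp counted as shared. That count was set against 1000 circular shifts within each arm, a one-sided permutation test for which the smallest p is 0.001. A gene counted as having a peak when an optimal summit lay within 1 kb of any of its annotated starts. The 32 gene lists were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. Gene biotypes were compared with protein-coding genes in the same way. Of the symbols written in the lists, 24 were not in the annotation under that name and were left out.

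Sequence words were counted on either strand within 50 bp of each summit and in windows of the same size centred 500 bp to each side. The exact McNemar test, two-sided, set the summit window against the flank at lower coordinates, and words were adjusted together. The link between signal and a word was tested with 100000 permutations. The genes named are those at the 20 strongest peaks, the 4 with the strongest peak in each list, and every Sox family member. A peak's gene is any protein-coding gene with a start within 1 kb of the summit, otherwise the gene whose body holds it, otherwise the nearest start. These lists, tests and rules were fixed before the data were examined.

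Alternatives covered the build, the 3527 strongest optimal peaks, each replicate alone, the distance that counts as shared, the length of the lists, the windows around starts, random gene lists matched on gene length and number of starts (10000 draws, a permutation of genes among strata), other motifs and windows, and peaks over 1 kb from a start. Older gene symbols, lists matched on promoter AT content, gene bodies with matched lists, comparisons at equal AT content, removal of closely spaced summits and removal of genes near protein-coding starts were chosen after seeing the data.

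The functions were tested on simulated data. For the overlap of replicates, 61.1% shared summits were recovered among 7055 where 60% had been planted. Over 13945 genes, simulated lists with 4-fold odds were called at an unadjusted p of 0.05 in 35% of cases with 8 genes, 86.5% with 25 and 100% with 90. Lists with no planted effect were called in 2%, 5% and 3.5%. Simulated lists were drawn at random and their genes given peaks independently, so these rates do not cover lists of neighbouring genes or genes that share a summit. A word planted in 300 of 2988 windows ranked first by p among 2080 words, and 0 words were called with none planted. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.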

Results

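Binding of Sox102F, the single SoxD-family member among the fly Sox genes examined here, was mapped in whole white prepupae, the stage at which the larva becomes immobile at the start of metamorphosis. SOX proteins bind DNA through an HMG domain. The 2 biological replicates came from 1 transgenic line with GFP-tagged Sox102F, and the labels imply a map of binding and its repeatability rather than a contrast of conditions. Signal values are the authors' own per peak. Sequencing depth is unknown, because the lists hold no read counts.

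Sox102F-GFP occupied 7055 optimal peaks on dm6, with a median signal of 135.4 and a median width of 430 bp. Peaks were spread over the large arms with small departures from their length and were sparse on chromosome 4, the small, largely heterochromatic chromosome that carries Sox102F itself. Chromosome 4 had 31 peaks, 0.441 times the 70.2 expected from its length (permutation test by random placement, two-sided, p = 0.002, the smallest possible). Its density was 17.1 per Mb in replicate 1 and 26.0 per Mb in replicate 4. The large arms ranged from 49.1 per Mb on 2R to 56.1 per Mb on X. Relative to length, 2R (0.931 times, placement permutation p = 0.00599) and 3R (0.959 times, permutation p = 0.032) had fewer peaks than expected. More were on 3L (1.06 times, permutation p = 0.012) and X (1.07 times, permutation p = 0.018), and 2L did not differ (1.02 times, permutation p = 0.352). These p-values were not adjusted for the number of arms. Placements scatter summits independently, while some optimal summits lie close together, so the p-values can overstate the evidence. The call for X ended with replicate 4 alone (1.03 times), in the 3527 strongest peaks (1.06 times) and on dm3 (1.01 times). The other large arms were not tested in these settings. Their replicate counts were set against the interval expected from placements. For 3R both replicates were inside it (1652 and 1634, interval 1627 to 1762). On 2R, replicate 4 was inside (1271, interval 1270 to 1396) and replicate 1 below (1230). On 3L, replicate 1 was inside (1531, interval 1407 to 1544) and replicate 4 above (1596).

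The same regions led both replicates. Of the 7055 strongest entries of replicate 1, 4802 (68.1%, Wilson 95% interval 67.0 to 69.1%) had a summit within 100 bp among the 7055 strongest of replicate 4. Circular shifts gave 1.06% on average and 1.64% at most (one-sided permutation p = 0.001, the smallest possible). Across the 6458 optimal peaks with an entry in both full replicate lists, the replicates' signals had a Spearman correlation of 0.73. These peaks were selected by pooled signal and by having an entry in both lists, and they are not independent replicates. The shares of unshared peaks near a start were compared after the values were seen, with 1 library on each side. In replicate 1, 2253 top entries had no summit within 100 bp among the 7055 strongest of replicate 4, whose weaker entries were not searched. Of these, 46.6% (Wilson interval 44.5 to 48.6%) were within 500 bp of a start. For the 2253 such entries of replicate 4 the share was 33.7% (31.8 to 35.7%).

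Sox102F-GFP peaks gathered at promoters and were almost missing from coding sequence. Within 500 bp of a transcription start lay 2571 summits (36.4%, Wilson interval 35.3 to 37.6%), against 13.6% of random placements, a 2.68-fold difference. The share was 40.3% in replicate 1 and 36.2% in replicate 4. Introns held 3047 summits (43.2%) and intergenic sequence 1253 (17.8%), against 39.5% and 27.1% of placements. Coding exons held 9 summits (0.128%) against 13.1% of placements. Shares in 3′ UTRs were also low, at 0.737% against 5.07%. All of these differed from placements (placement permutation test, two-sided p = 0.002, the smallest possible). Shares in 5′ UTRs (0.666%) did not differ from placements (0.780%, permutation p = 0.32), and other exons, those of non-coding transcripts, held 1.08% against 0.822% (permutation p = 0.008). Counted without the priority of other classes, 34 summits (0.482%) lay in a coding exon of any transcript, with 35 in replicate 1 and 37 in replicate 4. The intron excess did not hold with replicate 1 alone (1.02 times placements, permutation p = 0.0819) or with a start window of 1 kb (1.01 times, permutation p = 0.565). Against the 15000 weakest pooled entries it turned to 0.870 times.

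**Figure D1:**
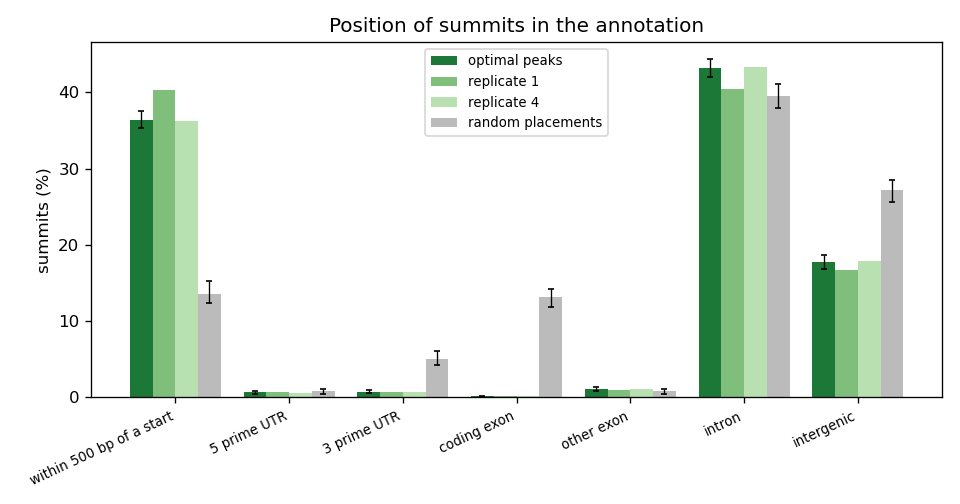
Share of summits (percent) in each annotation class for the optimal peaks, for the 7055 strongest entries of each replicate, and for random placements. Error bars are Wilson 95% intervals for the optimal peaks and the full range of 1000 placements for the grey bars. Summits near a start reach 36.4% against 13.6%, and coding exons 0.128% against 13.1%.

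Promoter summits sat mostly just upstream of the start. The median distance from an optimal summit to the nearest start was 1214 bp, against 3322 bp for placements (permutation p = 0.002, the smallest possible), with 949 bp in replicate 1 and 1220 bp in replicate 4. Shares within 100, 500 and 1000 bp were 14.2, 36.4 and 46.8%. Among summits within 500 bp, 71.0% lay upstream, and the median position was −91 bp. For the 15000 weakest pooled entries these values were 58.7% and −51 bp.

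The 20 strongest peaks included 12 with a summit within 500 bp of a start, 5 in introns and 2 in intergenic sequence. The strongest (3L, 19590406 to 19590830) lay 92 bp from a start of CG14100 (FBgn0036889), with a signal of 2702 and replicate signals of 1380 and 1335, for replicates 1 and 4. The next (2L, 6612358 to 6612952) lay in an intron of CG11050 (FBgn0031836), with a signal of 2540 and replicate signals of 1116 and 1420. The peak 79 bp from a start of PNPase and 584 bp from one of Gprk2 (3R, 31404456 to 31404878) had a signal of 2472 and replicate signals of 1223 and 1252. An intronic peak of ush (2L, 480860 to 481334), which encodes a zinc finger cofactor of GATA factors, had a signal of 2460 and replicate signals of 1182 and 1236. The others at starts belonged to Ugalt and eIF2Bbeta, CG1888, CenG1A and mRpS23, Chro and Ssl1, CG18549, larp, CG9147 and Fbw5, Tcs5 and CHMP2B, and gish. A Lk6 peak lay 967 bp from its start. Peaks in gene bodies lay in osa, which encodes a subunit of the Brahma chromatin remodelling complex, in Eip75B, an ecdysone-induced nuclear receptor, and in CG32772. The osa summit lay in an exon of a non-coding transcript. The remaining 3 had eEF1gamma, CG13323 and CG31668 as nearest protein-coding starts, at 5733, 11911 and 3756 bp, and the first lay 123 bp from the start of lncRNA:CR31044. Across all 20, signals ran from 1549 to 2702.

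Of 13945 protein-coding genes, 2829 (20.3%) had a summit within 1 kb of a start, against 3321 with replicate 1 and 2724 with replicate 4. The shares of the 32 lists ranged from 0 to 71.0%. A total of 8 lists had a higher share than other genes, 7 a lower one, and 17 did not pass the test. Long genes with several promoters catch more peaks, and against random lists matched on gene length and number of starts 4 of the 8 higher lists and 3 of the 7 lower ones passed. A summit near a start can also lie near the start of a neighbouring gene, so a list's share counts positions and not regulation. No list was matched on transcript level or promoter accessibility, and no untagged line was analysed. For every list, higher or lower, these cannot be told apart from targeting by Sox102F.

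Genes of the ecdysone response, the steroid hormone programme that drives metamorphosis, often had peaks. Of 31 genes, 22 (71.0%, exact 95% interval 52.0 to 85.8%) had a summit near a start, against 20.2% of other genes (log2 odds ratio 3.23, Fisher's exact test with Benjamini-Hochberg adjustment, p = 2.53e-08). The count was 21 in replicate 1 and 22 in replicate 4. The strongest were Sox14, a Sox gene induced by ecdysone, with a signal of 1253 and replicate signals of 597.2 and 656.6, and hid, a cell death gene, with 641.6, 285.5 and 344.7. Eip75B had 633.7, 260.0 and 365.1 in the same order, and the nuclear receptor gene Hr3 had 479.8, 219.3 and 268.0. Matched random lists gave 12.1 genes on average (permutation test, adjusted p = 0.0016, the smallest possible).

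Of 5 lists of signalling pathway genes, 4 had a higher share than other genes. The Notch pathway had 18 of 28 genes (64.3%, adjusted Fisher's exact p = 3.29e-06), led by the corepressor gro (signal 755.0, replicates 418.3 and 328.4), fng, aph-1 and E(spl)m7-HLH. The Hippo pathway, which limits organ growth, had 13 of 20 (65%, adjusted Fisher's exact p = 8.02e-05), led by the cadherin gene ds (994.0, replicates 506.0 and 484.8), ex, Diap1 and app. Both lists passed in each replicate and against matched lists (permutation test, adjusted p = 0.0016 and 0.0128). In the Notch list, the summits of gro and of all E(spl) genes with a peak lay on 3R from 25997317 to 26042499. Both tests count such neighbouring genes as independent, so the p-values for this list overstate the evidence. The EGFR pathway had 13 of 23 (56.5%, adjusted Fisher's exact p = 0.000559), led by the ligand gene spi (617.1, replicates 274.9 and 337.2), Raf, cic and aos. The Wnt pathway had 13 of 30 (43.3%, adjusted Fisher's exact p = 0.0134), led by gish (1549, replicates 664.1 and 882.7), sgg, fz3 and nkd. Both passed with each replicate alone, and neither EGFR (adjusted permutation p = 0.0935) nor Wnt (0.578) passed against matched lists. With gene bodies so matched, EGFR passed (adjusted permutation p = 0.0101) and Wnt did not (0.177).

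Most cytoplasmic ribosomal protein genes had a peak. A summit lay near a start of 61 of 93 (65.6%, exact interval 55.0 to 75.1%; log2 odds ratio 2.92, adjusted Fisher's exact p = 8.36e-20), with 70 in replicate 1 and 57 in replicate 4. The strongest were at RpS19b (750.5, replicates 383.2 and 365.3), 903 bp from its start, and at RpS27 (579.3, replicates 299.1 and 280.2), 1 bp from its start, followed by RpL7 and RpL32. Matched random lists gave 17.1 genes on average (adjusted permutation p = 0.0016, the smallest possible). Respiratory chain genes had 17 of 90 (18.9%, adjusted Fisher's exact p = 0.895), led by ND-ASHI, ND-75, ATPsynE and ND-MWFE. Proteasome genes had 2 of 48, Rpn5 and Rpn13, a lower share (4.17%, adjusted Fisher's exact p = 0.0105). The proteasome call ended with replicate 1 alone (6 of 48, adjusted Fisher's exact p = 0.157) and against matched lists (adjusted permutation p = 0.0935).

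Chromatin factors and glial markers passed with less margin. Chromatin factors had 13 of 32 (40.6%, adjusted Fisher's exact p = 0.0200), led by the Polycomb gene ph-p (signal 1274, replicates 719.2 and 618.0), brm, Dref and Trl. Glial markers had 7 of 15 (46.7%, adjusted Fisher's exact p = 0.0414), led by moody (461.7, replicates 255.1 and 211.0), Gli, Gs2 and pnt. Chromatin factors did not pass with replicate 4 alone (adjusted Fisher's exact p = 0.0519), in the 3527 strongest peaks (0.0626) or against matched lists (adjusted permutation p = 0.368). Glial markers passed in 2 of the 9 alternatives, and with neither replicate alone (adjusted Fisher's exact p of 0.123 and 0.157).

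Chemosensory receptor, cuticle protein and histone genes were among the lists with few peaks. Odorant and gustatory receptors had 3 of 119, Or88a, Or9a and Gr77a (2.52%, adjusted Fisher's exact p = 1.52e-07). Ionotropic receptors had 2 of 60, Ir94h and Ir52a (adjusted Fisher's exact p = 0.00102). Cuticle proteins had 5 of 119, led by Cpr72Eb, Cpr62Ba, Cpr47Ec and Cpr73D (adjusted Fisher's exact p = 4.41e-06). These 3 lists also passed against matched lists (adjusted permutation p = 0.0016, 0.0160 and 0.0412), and the cuticle call ended with gene bodies so matched (adjusted permutation p = 0.0877). Histone genes had 3 of 115, His2Av, His4r and His3.3B, all outside the repeated histone cluster (adjusted Fisher's exact p = 2.63e-07), and reads from repeated copies cannot be assigned to 1 copy. Cytochrome P450 genes had 8 of 81, led by Cyp6u1, Cyp310a1, Cyp6v1 and Cyp6a2 (adjusted Fisher's exact p = 0.0408). Salivary gland glue and late genes had 0 of 21, an exact upper bound of 16.1% (adjusted Fisher's exact p = 0.0321). In these lists too, genes that lie side by side, such as those of the histone cluster, were counted as independent. For lists with such genes, the p-values and exact bounds overstate the evidence. The histone, P450 and salivary gland calls ended against matched lists (adjusted permutation p = 0.0935, 0.311 and 0.578), and the P450 call was kept in 3 and the salivary gland call in 4 of the 9 alternatives. The last 2 calls also ended with replicate 4 alone (adjusted Fisher's exact p of 0.0523 and 0.0519), with starts within 500 bp and in the 3527 strongest peaks.

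Most lists of patterning genes and of other cell types did not pass. Hedgehog and Dpp genes had 9 of 23 (adjusted Fisher's exact p = 0.0661), led by shn, brk, wit and tkv, and imaginal disc patterning genes 8 of 29 (0.514), led by Dll, mirr, dac and tup. Eye genes had 5 of 18, led by so, dan, ey and oc, and tracheal genes 5 of 20, led by bnl, knk, trh and sha. Axon guidance genes had 9 of 26, led by unc-5, Sema1a, trio and robo2, and neuron markers 7 of 31, led by elav, Ank2, Rbp9 and Syx1A. Neuroblast genes had 7 of 29, led by brat, grh, hb and pros, with 3 in replicate 1 and 8 in replicate 4. Heart and mesoderm genes had 6 of 25, led by tin, sns, how and mid, and muscle genes 6 of 27, led by Msp300, Zasp52, Tm1 and Actn. Cell cycle genes had 9 of 25, led by stg, Dp, Mcm2 and fzr, and fat body markers 5 of 22, led by Apoltp, Ilp6, bmm and FASN1. Midgut markers had 2 of 18, pros and cad, hemocyte markers 1 of 15, ush, and testis genes 1 of 28, can. Adjusted p for these lists ranged from 0.0611 for testis genes to 0.849. Testis genes passed as lower with replicate 1 alone (adjusted Fisher's exact p = 0.0173), with starts within 500 bp (0.0281) and with older symbols matched (0.0298). Hedgehog and Dpp genes passed as higher with older symbols matched (adjusted Fisher's exact p = 0.0364), and disc patterning genes with replicate 4 alone (0.0489). With whole gene bodies counted, axon guidance (adjusted Fisher's exact p = 9.55e-05), Hedgehog and Dpp (0.0202) and heart and mesoderm genes (0.0488) passed as higher, and none of these 3 did with gene bodies matched on length (adjusted permutation p of 0.870, 0.669 and 0.870). Against matched lists, which gave 14.7 neuron markers on average, the direction turned and that list passed as lower (adjusted permutation p = 0.0247).

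The 8 Hox genes, which set segment identity, had no summit within 1 kb of a start, which allows a share of up to 36.9% (exact, adjusted Fisher's p = 0.518). With replicate 1 alone 1 of the 8 had a summit there, and with replicate 4 alone 0 had. With the whole gene body counted, 5 of the 8 had one, against 23.2% of other genes (adjusted Fisher's exact p = 0.0357). Against lists matched on length and starts, which gave 3.74 genes on average, the absence at starts passed (adjusted permutation p = 0.0288). Disc patterning genes likewise had 19 of 29 (65.5%, adjusted Fisher's exact p = 5.99e-06) with the gene body counted. Neither gene-body call held against lists matched on gene length and starts, which gave 5.09 Hox genes and 16.0 disc patterning genes on average (adjusted permutation p = 1 and 0.597).

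**Figure D2:**
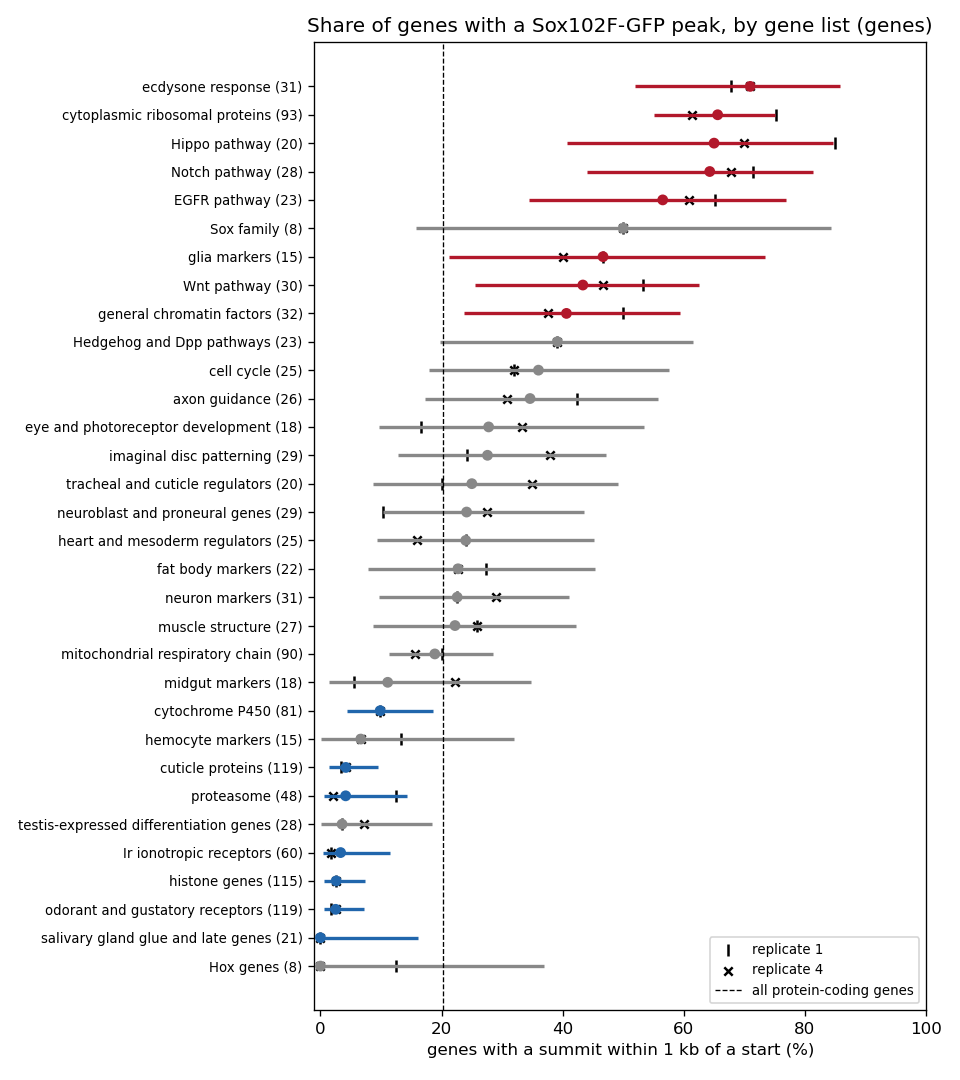
Share of genes (percent) with an optimal summit within 1 kb of a start for each of 32 lists, with the number of genes in brackets. Points are optimal peaks with exact 95% intervals, red for lists above other genes, blue for lists below, grey for lists that did not pass, and black marks are each replicate alone. The ecdysone list reaches 71.0% and the dashed line for all protein-coding genes is at 20.3%.

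Among Sox genes, 4 of 8 had a summit within 1 kb of a start (adjusted Fisher's exact p = 0.105), and the list passed in the 3527 strongest peaks (adjusted Fisher's exact p = 0.0344) but not in the other 8 alternatives. Lists matched on length and starts gave 2.84 genes on average (adjusted permutation p = 0.743). Sox14 had the strongest, followed by Sox102F (signal 364.2, replicates 137.1 and 213.5), D (183.0, replicates 72.0 and 112.1) and Sox21b (140.0, replicates 71.5 and 66.6). For SoxN, Sox15, Sox21a and Sox100B the nearest summits were 9369, 2528, 23647 and 2455 bp away.

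The tagged gene itself held several peaks. Within Sox102F (FBgn0039938, chromosome 4, 800436 to 834393, minus strand) and 2 kb on each side lay 5 of the 31 peaks of chromosome 4 (16.1%), in 2.82% of its length, a share noticed after the values were seen. The strongest summit, at 807582, was in an intron, 235 bp from an internal start, and another at 807786 was 204 bp from it, in an overlapping interval. Further intronic summits lay at 829961 and 833165, with signals of 145.9 and 103.2. A summit at 834788, upstream of the most distal start, had a signal of 122.5 and no summit within 100 bp in either replicate list. The line carries a tagged copy of this gene per the labels, and the number of copies of the locus is not given in the sources used here.

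**Figure D3:**
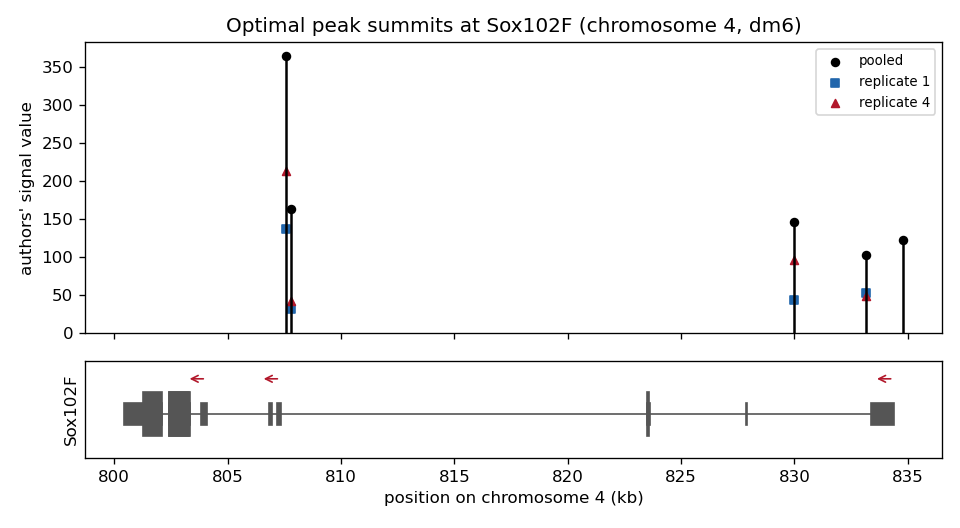
Authors' signal value of the 5 optimal summits at Sox102F by position on chromosome 4 (kb, dm6), pooled and in each replicate where a summit lay within 100 bp. The lower track shows coding exons as tall boxes, other exon sequence as low boxes and starts as arrows, and the strongest summit (364.2) lies beside an internal start.

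By gene biotype, protein-coding genes had peaks most often, in a comparison that was not matched on gene length or number of starts. Non-coding RNA genes had 524 of 3261 (16.1%, exact interval 14.8 to 17.4%, adjusted Fisher's exact p = 5.57e-08) and tRNA genes 42 of 290 (14.5%, adjusted p = 0.0217). Pseudogenes had 10 of 268 (3.73%, adjusted p = 4.59e-14) and rRNA genes 0 of 99, an exact upper bound of 3.66% (adjusted p = 1.27e-09), and reads from repeated copies in these 2 classes cannot be placed at 1 position. Neighbouring copies were also counted as independent genes. The snoRNA genes (43 of 269, 16.0%, adjusted Fisher's exact p = 0.110) and snRNA genes (4 of 32, adjusted p = 0.379) did not pass, but with a window of 500 bp the snoRNA share was 0.305 times that of protein-coding genes (adjusted p = 1.68e-08).

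The SOX core site AACAAT was slightly more frequent at summits than beside them. It occurred within 50 bp of 893 summits (12.7%, Wilson interval 11.9 to 13.5%), against 10.8% in the flanks, a ratio of 1.17. Of discordant peaks, 786 had it at the summit alone and 646 in the lower flank alone (exact McNemar test, two-sided, p = 0.000237). The ratios in replicates 1 and 4 were 1.18 and 1.14. Its ratio ranked 489 among 2080 words, and the longer AACAATG did not pass (ratio 1.03, exact p = 0.786). Compared at equal AT content, a comparison chosen after seeing the data, the direction turned: the ratio was 0.880 (bootstrap 95% interval 0.808 to 0.952).

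AACAAT did not follow peak strength. In 5 bins by signal its share was 14.5% in the strongest, 13.5% in the weakest and 11.0 to 12.2% in the others, with flanks from 9.32 to 11.5%. The Wilson intervals ran from 12.8 to 16.5% in the strongest bin and from 11.9 to 15.4% in the weakest. The Spearman correlation with signal across peaks was 0.0083 (permutation test, two-sided, p = 0.49). AT content at the summit rose with signal (Spearman correlation 0.217), and the AACAAT correlation was not adjusted for AT content.

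Summits were rich in A and T, and more so where binding was strong. Of 2080 words, 475 were more frequent at summits and 929 less frequent (exact binomial tests, adjusted p below 0.05). Among words in at least 1% of flanks, the highest ratios were those of ATATTA (2.17; 17.6% against 8.08%), ATCTTA (2.06) and TACTAA (2.05), and CCCAGG (0.680% against 2.13%) had the lowest. AT content within 50 bp of the summit averaged 64.3%, against 57.2% in the flanks, with 64.4% in replicate 1 and 63.6% in replicate 4. It was 68.1% in the strongest of the 5 bins and 62.4% in the weakest.

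**Figure D4:**
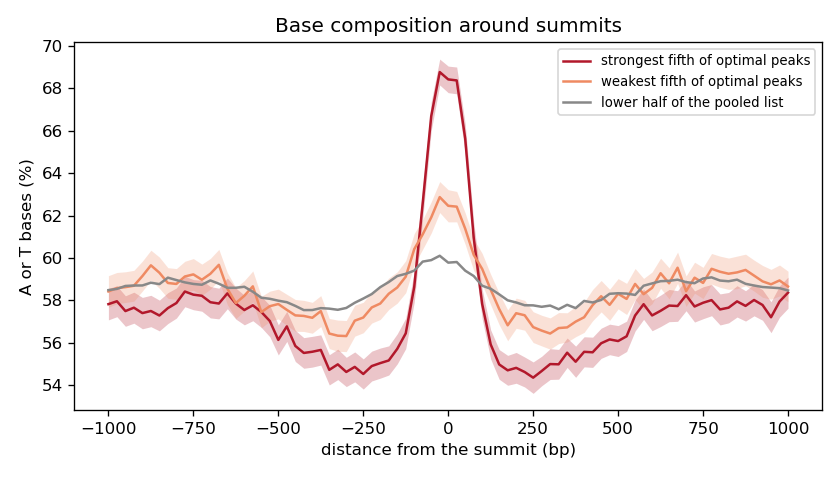
A or T bases (percent) in windows around summits by distance (bp), for the strongest and weakest of 5 signal bins and for the 15000 weakest pooled entries. Shading is the normal 95% interval over peaks, and AT content within 50 bp of the summit reaches 68.1% in the strongest bin.

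Of the preset words, the DREF and BEAF-32 site TATCGA was more frequent at summits (4.61% against 3.35%, adjusted exact p = 9.01e-05). GAGAGA, bound by GAGA factor, was also more frequent (6.82% against 5.19%, adjusted exact p = 0.000103). It was not in the 3527 strongest peaks (5.53% against 5.80%, adjusted exact p = 0.842) or in peaks over 1 kb from a start (adjusted exact p = 0.227). Its share was 4.25% in the strongest bin and 7.58% in the weakest. The E-box words CAGCTG (3.44% against 4.31%, adjusted exact p = 0.00569) and CACGTG (0.780% against 1.07%, adjusted p = 0.0438) were less frequent, as were TGACTC (adjusted p = 0.0478) and ATTTGC (adjusted p = 0.00420). Summits are AT-rich, and words with 2 A or T bases had a median ratio of 0.660, below CAGCTG (0.80) and CACGTG (0.731), so relative to their composition the direction of these 2 turned. In peaks over 1 kb from a start it did not turn, with 0.560 for CAGCTG and 0.434 for CACGTG, below a median of 0.569. Words with 3 A or T bases had a median ratio of 0.837, near TGACTC (0.797) and below GAGAGA (1.31). For words with 4 it was 1.15, below TATCGA (1.37) and above ATTTGC (0.870). Over 1 kb from a start, TATCGA (1.27) was close to its median (1.22), and TGACTC (0.656) was below its own (0.816). In the 3527 strongest peaks CACGTG (adjusted exact p = 0.0926) and ATTTGC (0.238) did not pass. Among all optimal peaks CAGGTA (adjusted exact p = 0.233) and GTCACA (adjusted exact p = 1) did not pass, and CAGGTA was less frequent in the strongest peaks (0.0474).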

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

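The tests in this part were chosen after the results were seen, except the lists matched on gene length and starts. With 1 group, no biological explanation was tested by a contrast of groups. On dm3, 8 optimal peaks lay on sequences outside the 6 arms, which no comparison used: 5 on Uextra and 1 each on U, XHet and 3LHet, with signals up to 152.1.

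AACAAT, the SOX core site, was more frequent at summits than in the flanks by a ratio of 1.17. The AT-rich composition of the summits is a candidate explanation: against flank windows of equal AT content the ratio was 0.880 (bootstrap 95% interval 0.808 to 0.952). That interval lies below 1, so AT content predicted more summits with AACAAT (14.4%) than were seen (12.7%), and it does not describe the share exactly. Across all peaks AACAAT was not favoured over words of its base composition, since 26 of the 29 others had a higher ratio. Positions 500 bp from the summit lay in coding exons more often than summits (8.90% against 0.482%), and this was not matched. The rank of AACAAT therefore does not decide on a preference for it. Binding to AACAAT at a minority of peaks, to other sequences or through partner proteins stays open.

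Ribosomal protein genes had summits near the starts of 61 of 93. Promoter AT content does not account for this, since lists matched on it gave 18.8 genes on average (adjusted permutation p = 0.00107, with 0.0016 for lists matched on gene length and starts). The other 2 housekeeping lists examined did not share the pattern. Respiratory chain and proteasome genes together had 19 of 138 (13.8%, exact interval 8.50 to 20.7%), below the 55.0% that bounds the ribosomal protein share. These lists, like that of ribosomal proteins, were drawn by symbol pattern and can include paralogs of narrow expression. They do not decide on housekeeping transcription in general. Transcript levels were not used here, so very high transcription, or promoter accessibility that attracts many proteins or the antibody, stays open.

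Summits were rare in coding exons, at 0.482% (Wilson interval 0.345 to 0.673%). Base composition is not the whole cause, since random positions of the same AT content were in coding exons in 8.51% of cases. Nor is placement at promoters, because among summits over 1 kb from a start the share was 0.186% (0.0903 to 0.384%), against 14.1% of random positions there. Nor is the authors' threshold, because the 22945 weaker pooled entries were at 1.94% (1.76 to 2.12%), against 17.2% at random positions. Open chromatin outside coding sequence, and the control used in calling peaks, stay open.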

How the results depend on the processing

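Depth is unknown, and 2 replicates allow no outlier test. With either replicate left out, 1 remains, so the overlap and the Spearman correlation of the signals have no value there, and biotypes were not run that way. No paired analysis was possible because there is 1 group. Comparisons at equal composition, at equal promoter AT content, with older symbols, with matched gene bodies and without nearby protein-coding starts were chosen after seeing the data. Replicate overlap ranged from 54.0% within 50 bp to 76.6% for any overlap of intervals, above all shifts in each case. The Spearman correlation of the replicates' signals was 0.70 within 250 bp and 0.78 within 50 bp. The stricter list held 3527 peaks by construction. The ratio for X no longer passed there (1.06) or on dm3 (1.01), and without 1 replicate it ran from 1.03 to 1.07. The intron ratio was 1.01 with a start window of 1 kb, 0.870 against weak pooled entries, and 1.02 to 1.10 without 1 replicate. The snoRNA share relative to protein-coding genes passed at 0.305 with 500 bp and 0.217 away from protein-coding starts. For the latter, genes near protein-coding starts were removed from the snoRNA genes alone, and protein-coding genes stayed at 2829 of 13945. Summits gather at starts, so that filter by itself favours a lower ratio, and the 0.217 is not a like comparison. Lists with a higher share numbered 4 when matched on gene length and starts, 5 with gene bodies so matched, and 7 to 12 otherwise. Lists with a lower share numbered 3 with matched gene bodies and 5 to 8 otherwise, and the 5 against matched lists included Hox genes and neuron markers. Of 288 values for single lists, 218 kept direction and side of the threshold, 31 no longer passed, 11 newly passed and 28 changed direction, most without passing in either setting. On the log2 scale, the lists that turned against matched lists were neuron markers (−1.02), muscle (−0.74), disc patterning (−0.50), tracheal (−0.31), heart (−0.30), neuroblast (−0.23), eye (−0.14), axon guidance (−0.12) and respiratory chain genes (0.23). With matched gene bodies these were muscle (−0.75), neuron (−0.65), fat body (−0.14), eye (−0.062) and respiratory chain genes (0.29). With gene bodies alone they were Hox genes (2.38) and midgut markers (0.43). In the 3527 strongest peaks they were disc patterning (−1.51), heart (−1.29), tracheal (−0.96), eye (−0.80), neuroblast (−0.18) and axon guidance (−0.0056). Without 1 replicate the values ran from −0.47 to 1.10 for eye, −0.21 to 0.093 for heart, −0.031 to 0.80 for neuron, −1.25 to 0.70 for neuroblast, −1.87 to 0.35 for midgut and −0.20 to 1.196 for tracheal genes. The AACAAT ratio was 1.03 for AACAATG, 0.844 relative to words of its composition and 0.880 at equal AT content. GAGAGA turned to 0.954 in the 3527 strongest peaks and GTCACA to 0.929 in peaks over 1 kb from a start. The correlation of signal with AACAAT turned to −0.00096 with 100 bp on each side. The cause was not tested, except where a shorter list or a matched background is the change itself.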

Other observations

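All counts in this part were chosen after the data were seen. Some long genes held many summits. The gene bodies with the most were kirre (32 summits in 394.1 kb), Tet (31 in 93.0 kb), sbb (28 in 79.1 kb) and Eip75B (25 in 113.7 kb). Mnt, which encodes a partner of the transcription factor Max, had 21 in 29.9 kb, or 7.03 per 10 kb, against 0.527 per 10 kb over the arms. The gene bodies of ush (18), psq (17), shn (17) and mam (16) followed among known transcriptional regulators.

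The share of summits in coding exons returned gradually with distance. It was 0.482% at the summit, 2.69% at 200 bp, 8.90% at 500 bp, 12.5% at 1000 bp and 18.2% at 5000 bp, averaged over both sides.

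Closely spaced summits made up part of the list. Of neighbouring optimal summits, 466 pairs (6.61%) lay within 430 bp, with a median gap of 203 bp and a smallest gap of 199 bp, and 36 intervals occurred with a second summit.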
